A study of Enterococcus faecium with 4 samples.

How the data were processed

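Ribosomal RNA was removed from total RNA with a bead-based depletion kit for Gram-positive bacteria, per the labels' protocols, and strand-specific (dUTP) libraries were sequenced as single-end reads of 50 bases on an Illumina HiSeq. The labels give the molecule as polyA RNA, although the protocol describes ribosomal RNA depletion. The deposited table of each library lists, per locus tag, a gene length, a count of unique gene reads, a count of total gene reads and an RPKM value, per the file headers. Both count columns are whole numbers and are equal in all 2860 rows (0 rows differ), and the column of total gene reads was used. The deposited RPKM values were computed by the authors per kilobase of gene length and relative to a read total. That total follows from count, length and RPKM, is one value within each table, and was 13233117 and 6927541 reads without caspofungin and 14720219 and 15574123 reads with it. The submitters' processing notes name DESeq2 without a role or version. The aligner, the counting tool and the genome build are not given in the sources used here. Each gene length is a multiple of 3 and is called coding length. Rows for ribosomal or transfer RNA were not identified, and 7 numbers between the first and last locus tag have no row.

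No table that pairs locus tags with gene names, products or coordinates was used here. Gene lists by function had been fixed before the data were examined and could not be applied, so no gene set test was run. Under the naming rule fixed at the same time, at most 2 identifiers are named in each direction when names cannot be had. They are the genes with the largest and the lowest log2 fold change among those with an adjusted p under 0.05, a mean of at least 10 CPM and both treated libraries on one side of both untreated ones. Neighbouring genes that moved the same way are given as runs.

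Groups were taken from the sample titles: 2 libraries without caspofungin and 2 with 8 mg/L. Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): genes were kept by filterByExpr with a minimum count of 10, which left 2348, scaled by TMM, and tested with estimateDisp, glmQLFit (robust) and glmQLFTest on a group-only design. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. The counts-per-million scale (CPM) was taken over the counts on the listed genes, without TMM factors, so a ratio of CPM means differs slightly from the fitted fold. The common biological coefficient of variation was 0.107. Replicates correlated at a Pearson r of 0.993 (untreated) and 0.995 (caspofungin) in log2(CPM + 1), and libraries of different groups at 0.926 to 0.947. The counts of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 10.3 and 52.0, so each library counted as 1 replicate.

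The test was checked on simulated counts with the mean levels, library sizes and fitted spread of these libraries and 200 changed genes among 2326 tested. It recovered 40.3% of the 1.41-fold changes, 92.5% of the 2-fold changes and 100% of the 4-fold changes, and 6 of its 161 calls were unchanged genes. Fewer genes changed there than the 60.3% called in these data, rises and falls were balanced, and no shift in library scale was simulated. Its recovery and error shares need not hold here. Neighbour relations were tested by shuffling calls or fold changes over the tested genes 10000 times, and relations to length and abundance by 100000 permutations across genes, in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. The neighbour, length and window descriptions were chosen after the data were seen.

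The alternatives tried were DESeq2 size factors, library totals alone and upper-quartile factors in the same fit, no low-count filter, a group mean of at least 50 counts, the DESeq2 1.42.0 Wald test, limma-voom, the sample number as a block, and leaving out each library in turn. Added after the data were seen were the read totals behind the RPKM, totals without the 10 most abundant genes, and thinning each library to the smallest total.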

Results

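RNA-seq counts per gene were analysed for 4 libraries of Enterococcus faecium Aus0004, a vancomycin-resistant strain of an intestinal Gram-positive coccus that causes hospital infections. The bacteria were grown at 37 °C in brain heart infusion broth to late exponential phase. For 2 libraries the broth held caspofungin at 8 mg/L, a dose below the one that stops growth, and for the other 2 it held none. Caspofungin is an echinocandin, an antifungal drug that blocks the synthesis of beta-glucan in the fungal cell wall. The comparison asked which transcripts of the bacterium differ in abundance when it grows in the presence of the drug. The libraries without caspofungin held 5564406 (replicate 1) and 3047906 (replicate 2) counts on 2860 listed genes, and those with caspofungin held 8250650 and 8730486. At these depths a gene with no count lies below 0.984 on the counts-per-million (CPM) scale in the shallowest library and below 0.344 CPM in the deepest, a limit of 3 counts that covers counting error only. The genes are identified by locus tag alone, so no gene below has a name, a product, a strand or a coordinate, and no pathway was tested. The number in a tag is used as the gene's place in the order of the genome's genes.

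Caspofungin was accompanied by a wide change in transcript abundance. Of 2348 genes tested, 715 were higher and 701 were lower with the drug, together 60.3% of those tested. At least 2-fold differences were seen in 340 genes that rose and 285 that fell, and at least 4-fold ones in 63 and 70 genes. The 5th and 95th percentiles of the log2 fold change were -1.52 and 1.67, against a median standard error of 0.17 on that scale. These calls come from edgeR's quasi-likelihood test on counts with TMM scaling and Benjamini-Hochberg adjusted p under 0.05, with n = 2 libraries per group. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. No gene with 0 counts in both libraries of one group reached 10 counts in both libraries of the other.

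**Figure D1:**
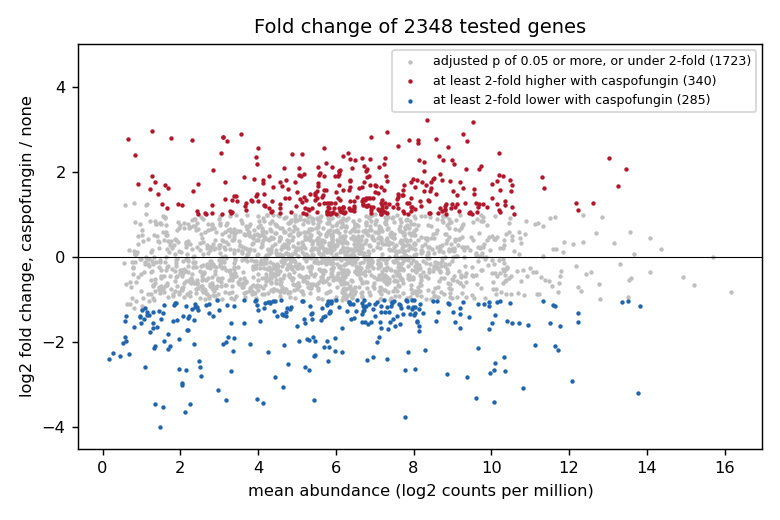
Each point is one of the 2348 tested genes, with its mean abundance in log2 CPM on the x axis and its log2 fold change with caspofungin against none on the y axis. The 340 red genes were at least 2-fold higher and the 285 blue genes at least 2-fold lower at an adjusted p under 0.05. None of the 10 genes with the highest fitted abundance was at least 2-fold higher, and 2 of them were at least 2-fold lower.

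The gene with the largest rise among those with a mean of at least 10 CPM was EFAU004_01702, a gene with a coding length of 591 bases. Its level was 58.8 ± 1.48 CPM (SD, n = 2) without and 604 ± 85.7 CPM (SD, n = 2) with caspofungin. In the TMM-scaled fit this was a 9.27-fold rise, a log2 fold change of 3.21 with a standard error of 0.15 and an edgeR adjusted p of 7.93e-11. EFAU004_01702 did not move alone. The gene next below it in number rose 5.93-fold and the one below that rose 4.24-fold, while the gene next above it rose 7.10-fold, so 4 adjacent genes were at least 2-fold higher. The gene with the next largest rise, EFAU004_00859 (1461 bases), went from 141 ± 14.1 to 1395 ± 202 CPM (SD, n = 2 each). Its log2 fold change was 3.16 with a standard error of 0.16 and an edgeR adjusted p of 1.09e-10, an 8.95-fold rise. The 3 genes numbered just below EFAU004_00859 rose 5.43-fold, 6.74-fold and 7.66-fold, which makes a second run of 4. The gene directly above EFAU004_00859 rose by 1.36-fold.

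The deepest fall under the same rule was that of EFAU004_00937, a gene of 2016 bases. It dropped from 396 ± 28.8 CPM to 32.3 ± 11.4 CPM (SD, n = 2 each), a log2 fold change of -3.76 with a standard error of 0.20 and an edgeR adjusted p of 1.9e-10, or 13.5-fold. The 2 genes numbered above EFAU004_00937 fell 8.72-fold and 4.35-fold. In contrast, the 2 genes numbered below EFAU004_00937 rose, the adjacent one 7.43-fold, from 139 ± 37.2 to 1136 ± 274 CPM (SD, n = 2 each), and the next one 4.09-fold. EFAU004_00887, of 1260 bases, fell from 34.9 ± 2.49 to 3.63 ± 2.06 CPM (SD, n = 2 each). Its log2 fold change was -3.42 with a standard error of 0.29 and an edgeR adjusted p of 1.74e-08, a 10.7-fold fall. EFAU004_00887 was read at only 42 and 19 counts in the caspofungin libraries, and its log2 fold change was -4.17 when caspofungin replicate 1 was left out. The gene next above EFAU004_00887 fell 4.38-fold, from 4.21 ± 0.39 to 1.08 ± 0.88 CPM (SD, n = 2 each). At that low level its log2 fold change had a standard error of 0.51. The gene next below EFAU004_00887 had too few reads to be tested.

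**Figure D2:**
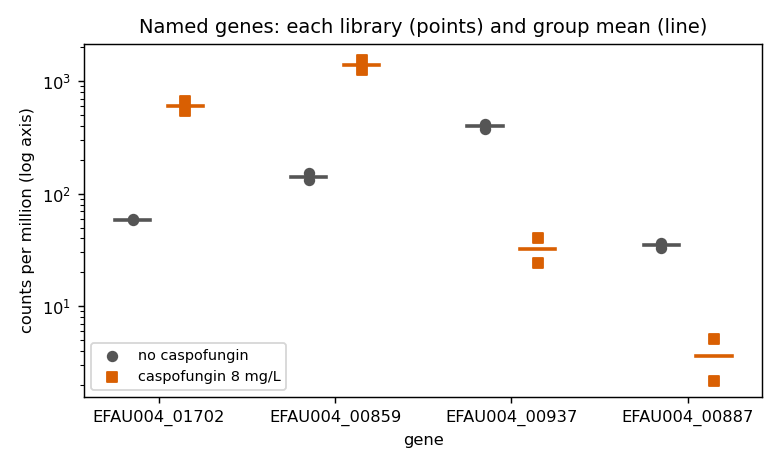
CPM, on a log axis, of the 2 genes with the largest rise and the 2 with the deepest fall under the naming rule, which asks for a mean of at least 10 CPM. Points are single libraries and lines are means of 2 libraries, grey without and orange with 8 mg/L caspofungin. That both treated libraries lie on one side of both untreated libraries in each gene was required by the same rule.

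Genes that changed lay beside genes that changed the same way far more often than random placement gives. There were 25 runs of at least 3 consecutively numbered genes that all rose at least 2-fold, holding 87 of the 340 such genes. Shuffling the calls over the tested genes gave 5.19 such runs on average. Of the genes that fell at least 2-fold, 105 of 285 lay in 28 runs of at least 3, where shuffling gave 3.11 runs. The longest runs, singled out after their values were seen, had 7 genes each. The rising one spanned gene numbers 1964 to 1970, with folds from 2.22 to 4.54, and the falling one spanned numbers 345 to 351, with folds from 2.06 to 6.24. Neighbouring pairs that both passed the 2-fold threshold moved the same way in 206 cases and opposite ways in 38, where shuffling gave 76.4 and 75.5. Each of these 6 quantities had a two-sided permutation p of 0.0002, the smallest that 10000 shuffles can give, and the same value after Benjamini-Hochberg adjustment. Across genes, which are not independent replicates, the fold changes of adjacent genes had a Pearson correlation of 0.41 over 2147 pairs. It was 0.21 at a distance of 2 gene numbers, 0.11 at 3 and 0.07 at 5 (adjusted permutation p of 0.0002, 0.0002, 0.0002 and 0.0054 for distances 1, 2, 3 and 5). At distances of 10 and 20 it was 0.0013 and 0.022, with adjusted permutation p of 0.95 and 0.4. Differences between replicates of a group also ran together in places, as in many genes numbered 101 to 150, which were higher in untreated replicate 2 than in replicate 1. How far such differences cluster along the whole gene order was not tested, so the clustering is not shown to be particular to the drug. When only genes with a mean of at least 50 counts in each group were tested, the genes in rising runs numbered 36. With library totals alone as the scale, 124 genes lay in rising and 62 in falling runs, and with the read totals behind the deposited RPKM values 265 and 39, so that on both of these scales rising runs held more genes than falling ones.

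Over longer distances the regions of the gene order differed too. In windows of 50 gene numbers, the lowest median log2 fold change was -0.86. It was that of the 50 tested genes numbered 101 to 150, of which 15 fell and 1 rose at least 2-fold. Many of these genes also differed together between libraries with the same treatment, being higher in untreated replicate 2 than in untreated replicate 1. In many of them both caspofungin libraries still lay below both untreated ones. How far the difference between the untreated replicates shapes this median was not tested. The windows of numbers 51 to 100 and 301 to 350 had medians of -0.73 and -0.64. Among windows with at least 20 tested genes the highest median was 0.54, for numbers 1701 to 1750, where 18 of 48 tested genes rose and 4 fell at least 2-fold. It was followed by 0.52 for numbers 1951 to 2000, with 13 rising and 2 falling.

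**Figure D3:**
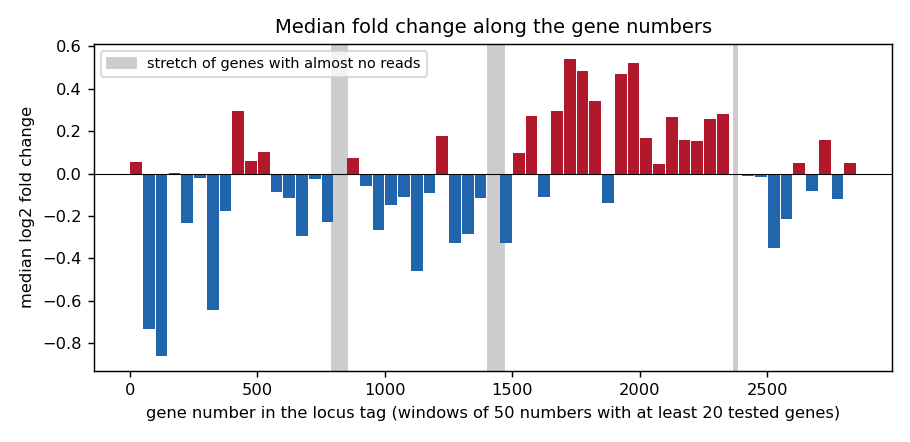
Median log2 fold change with caspofungin against none in windows of 50 gene numbers (x axis: gene number in the locus tag), for the 54 windows with at least 20 tested genes; grey bands are stretches of genes with almost no reads in any library. Medians were below 0 in 20 of 27 windows below the middle number (1433.5) and above 0 in 18 of 27 windows above it.

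Short genes and long genes also differed. Among the 588 tested genes with the shortest coding length (93 to 504 bases), 131 genes rose and 72 fell at least 2-fold, and the median log2 fold change was 0.17. Among the 587 longest (1221 to 4938 bases), 41 rose and 87 fell, and the median was -0.19. Across genes the fold change went down with coding length (Spearman's rho -0.13, Pearson's r -0.14 with log2 length, permutation p = 1e-05, the smallest that 100000 permutations can give). The difference between the 2 caspofungin replicates had a relation to length of the same sign (rho -0.18, permutation p = 1e-05), and for the difference between the untreated replicates rho was 0.01 (permutation p = 0.622). A relation of this size thus also arose between libraries with the same treatment. The permutations treat genes as independent and do not measure the spread between libraries, so the relation cannot be tied to the drug. After Benjamini-Hochberg adjustment over the 6 relations computed, the permutation p-values for length were 2e-05 for the fold change, 2e-05 for the caspofungin replicates and 0.622 for the untreated replicates. The remaining relations were with abundance. Spearman's rho was 0.10 for the fold change, 0.08 for untreated replicate 2 minus replicate 1 and -0.04 for caspofungin replicate 2 minus replicate 1. Their adjusted permutation p-values were 2e-05, 7.5e-05 and 0.0462. A relation to abundance of similar size thus also arose between the untreated libraries.

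Of the 10 most abundant genes in the fitted abundance, 5 were lower and 1 was higher with caspofungin, and 4 did not pass the test. Fold changes among these 10 ran from 9.15-fold lower to 1.36-fold higher. The 10 genes with the highest mean CPM took 32.5% and 32.6% of the counts on the listed genes without the drug, and 26.6% and 25.1% with it. Relative to the read totals behind the RPKM no such fall was seen.

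The balance of rising and falling genes depended on the scale. The deposited RPKM values rest on a read total per library that is larger than the counts on the listed genes. The listed genes made up 42.0% (95% Wilson interval 42.0 to 42.1) and 44.0% (44.0 to 44.0) of that total without caspofungin, and 56.0% (56.0 to 56.1) and 56.1% (56.0 to 56.1) with it. The group means were 43.0% ± 1.38 and 56.1% ± 0.0055 (SD, n = 2 each). An exact two-sided permutation test gave p = 0.333, the smallest that 2 libraries against 2 allow, so the difference could not pass a threshold of 0.05 in this test. The intervals cover counting error only, and the untreated replicates lay 1.95 percentage points apart. With TMM scaling the median log2 fold change of the tested genes was -0.02. With the read totals behind the RPKM as the scale it was 0.51, 1211 genes were higher and 285 lower, and 80.9% of the called genes were higher in place of 50.5%. With the totals of the listed genes alone the median was 0.13, and 66.7% of the genes called at 2-fold were higher in place of 54.4%. Such a change of scale shifts the genes together, so the signs of the window and class medians above hold relative to the TMM scale only. The 4 genes named above kept their direction on each of these scales.

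**Figure D4:**
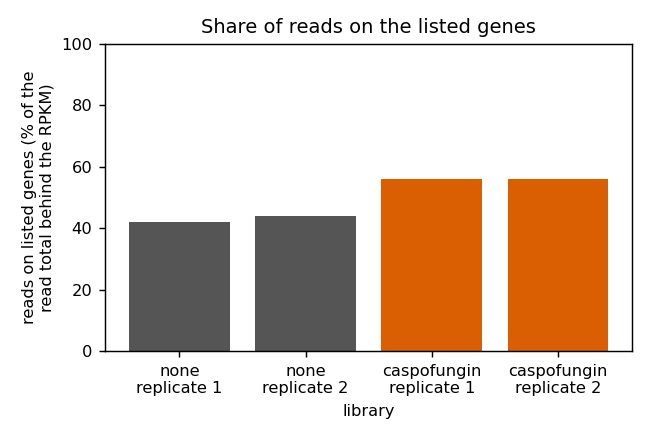
Share of the read total behind the deposited RPKM values that fell on the 2860 listed genes, in percent, one bar per library (grey without, orange with caspofungin). Both caspofungin libraries stand near 56.1% and the untreated ones at 42.0% and 44.0%.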

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

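The tests in this part were chosen only after the result was seen. The share of the authors' read total that fell on the listed genes comes from a column that the gene-wise comparison does not use, and it was higher with the drug than in the untreated libraries: 56.05% on average against 43.0%, a gap of 13.0 percentage points where replicates differed by at most 1.95. The tables argue against library depth as the source, since the untreated and the treated library nearest in read total (13233117 and 14720219 reads) still differed by 14.0 points. A few dominant transcripts among the listed genes do not account for the gap either, which was 12.57 points without the 10 most abundant of them. Dominant transcripts outside the listed genes could not be examined. What stays open is what the reads outside the listed genes were, 13.03 points more of the total in the untreated libraries. Residual ribosomal RNA, transfer RNA, intergenic reads and reads matching several places cannot be told apart here, because the tables hold no row for any of them. Whether the drug itself changes the ratio of messenger to other RNA is untested.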

How the results depend on the processing

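Of 179 values recomputed for 12 results under 15 alternatives, 171 kept their direction and their side of the threshold, or stayed within 1.5 times the main count. The other 8 were counts. Part of the agreement was given in advance. The neighbour correlation and the rho with length can hardly move when only the scale of a library changes. The 4 named genes had been picked for the size of their change in these same data. With the read totals behind the RPKM as library sizes, 1211 genes were higher and 285 lower, 705 and 116 of them at least 2-fold, and 265 and 39 genes lay in rising and falling runs. The whole distribution shifts there by construction, since one factor per library is applied. Library totals alone also apply one factor per library, and 124 genes then lay in rising and 62 in falling runs. With group means of at least 50 counts 36 lay in rising runs, where fewer genes were tested (1788). Leaving out each library in turn gave 583 to 710 genes higher and 572 to 695 lower, 286 to 375 and 260 to 328 at 2-fold, 63 to 87 genes in rising and 92 to 111 in falling runs, a rho with length of -0.15 to -0.10 and a neighbour correlation of 0.37 to 0.42; the lone library of a group was then assumed to vary like the other group. The sample numbers in the titles are not said to mark a shared culture or day. With the number as a replicate block, 749 genes were higher and 726 lower, 338 and 286 at 2-fold. Across the tested genes, the difference between libraries 1 and 2 without caspofungin correlated at 0.14 with the same difference with caspofungin. With only 2 such pairs of libraries, that leaves the pairing undecided. DESeq2's Wald test gave 636 and 581 genes (204 adjusted p-values were not available), and thinning to the smallest library gave 644 and 643. The 4 named genes kept their direction and their call wherever they were tested; EFAU004_00887 fell under the filter at a group mean of 50 counts, and its log2 fold change was -4.17 without caspofungin replicate 1, -2.91 without caspofungin replicate 2 and -2.89 with the read totals behind the RPKM. The gene set tests, the alternative without ribosomal and transfer RNA rows, and those for normalized values were not run, since no such rows or names were identified and counts were deposited. With 2 libraries per group, no regrouping of libraries was counted.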

Other observations

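The tests in this part were chosen only after the result was seen. Parts of the genome could not be read at all from the deposited counts. The 62 genes numbered 793 to 854 held 3 reads and the 63 genes numbered 1404 to 1466 held 0 reads, out of 25593448 reads in all 4 libraries. Of the 228 genes at 0 in every library, 123 lie in the matched part of these stretches. The run of 4 rising genes that ends at EFAU004_00859 starts 2 numbers above the first stretch.

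The coding lengths of genes 793 to 854 are those of genes 1466 to 1405 in mirrored order, without exception over 62 consecutive genes (35715 coding bases in each copy). With genes 793 to 854 left out of the search, the longest mirrored match is 3 genes. A further match in the same order, of 14 genes, joins the second stretch to numbers 2372 to 2385, which held 5 reads. Through the second stretch, part of genes 793 to 854 must mirror those numbers too. A candidate explanation is that one region is present in inverted copies and that reads matching more than one copy were left out of both count columns, which would fit 62 matching lengths. Whether the genes are also silent, or were lost from the cultured strain, cannot be told apart from this, since 3 reads in all libraries is what each would give. Elsewhere, 61 of the 105 other genes at 0 have a partner of equal length among these 105. Random sets of 105 genes with reads gave 17.9 on average (permutation p = 0.0001, the smallest that 10000 draws can give). The random sets were not matched for length. None of the genes at 0 has a fold change here.

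Genes numbered above the middle of the numbering (1433.5) lay higher with caspofungin than those numbered below it. Below the middle 136 genes rose and 191 fell at least 2-fold, and above it 204 rose and 94 fell. The part above the middle was not uniform. Medians were above 0 in 18 of its 27 windows, but -0.35 and -0.21 for numbers 2501 to 2550 and 2551 to 2600. The mean log2 fold change was 0.30 higher above the middle. Over random orders of blocks of 50 genes this difference had an SD of 0.08, which holds no spread between libraries. All 4 treated-against-untreated pairs of libraries showed the difference, from 0.24 to 0.32. These pairs reuse the same 4 libraries and are not independent. A scaling by one factor per library cannot change this difference.

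Between replicates of a group the same difference was at most 0.0752. Those replicates may not be separate cultures, so variation between cultures stays open as the source. Within 4 classes of coding length the difference between the sides of the middle was 0.305, which argues against gene length. Clusters of neighbouring genes placed by chance were tested by letting the split fall anywhere in 10000 random orders of blocks, which gave a permutation p of 0.0007. A gene dosage gradient that follows the distance from the nearer end of the numbering is symmetric about the middle. It would move both sides nearly alike and could hardly give this difference. For the same reason that distance, used as a covariate, could not have moved the difference, which was 0.304 with it. A gradient from a replication origin that is not symmetric about the middle stays open, since the place of the origin is not given. A difference in gene content or strand between the regions may be involved too, and neither was tested, as the tables give no strand or function.

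Caspofungin replicate 2 lay farther from the untreated libraries than replicate 1 in 489 of the 625 genes called at 2-fold, 288 of 340 that rose and 201 of 285 that fell. The SD over genes of the log2 CPM difference from the untreated mean was 0.869 for replicate 1 and 0.992 for replicate 2.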
